A study of Mus musculus with 16 samples.

How the data were processed

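CUT&RUN for CREB, with IgG as control, was run on astrocytes isolated from mouse brain after 7 days of saline or cocaine (20 mg/kg) and 24 h of withdrawal, per the labels. Libraries were made from genomic DNA with an Illumina kit, per the labels' protocols. The labels put the 16 libraries in 4 groups of 4 (cocaine CREB, cocaine IgG, saline CREB and saline IgG), numbered as replicates. Whether each library came from a separate animal is not given in the sources used here. The submitters' processing notes name HISAT2, Picard, deepTools, ChIPseeker and the mouse build mm10, without versions. Peak names in the deposited lists point to MACS as the caller, and its version is not given in the sources used here.

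The deposited values are 1 peak list per treatment, with start, end and summit of each peak. How the replicates were combined, how the IgG libraries entered and the depth per library are not given in the sources used here. The deposited fold of each peak is a ratio of its summit over the caller's background. The deposited p and q of each peak are given as −log10 values, and every peak had a −log10 q of at least 2. The deposited score of each peak is 10 times its −log10 q, and it was not used for any result. No list holds values per sample, so the 2 lists were compared as they stand, with no p-value between treatments. The number of columns with per-sample values left unused is therefore 0.

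From fold and p the number of reads at each summit and the background were recovered with the Poisson model and the pseudocount of 1 that MACS uses. A whole number of reads met the deposited p within 0.01 on the −log10 scale in 99.7% of cocaine and 99.3% of saline peaks. Recovered heights ranged from 5 reads up in the cocaine list and from 6 up in the saline list. The whole numbers show that the CREB reads were not scaled before calling. Of the peaks on the chromosomes compared, 37.8% in the cocaine list and 60.4% in the saline list had 8 or fewer reads, so a single weak peak rests on few reads and a missing peak does not show that CREB was absent. The number of peaks a caller returns depends on depth, pull-down and background, and each of these can move the comparison between lists.

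Comparisons used chromosomes 1 to 19, X and Y, with 2416 of 2447 cocaine and 1040 of 1085 saline peaks. Genes came from the RefSeq annotation of the same build, which gave starts and ends for 21887 protein-coding genes on these chromosomes. Strand, exons and the genome sequence were not used here. The planned window of 3 kb around transcription start sites was therefore replaced by 3 kb around either gene end, and each summit was given to the protein-coding gene with the nearest end. Planned searches for the CREB motif and other motifs, exclusion of repeats and matching on CpG content were not run. Random gene lists were matched on gene length in 5 classes in place of CpG content. Named peaks at repeats could for the same reason not be left out.

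Peaks were shared when they overlapped by at least 1 bp. Chance overlap and chance closeness to gene ends came from 1000 random placements of each list between the first and the last gene of each chromosome. Shares have exact 95% Clopper-Pearson intervals. Shared and other peaks within a list were compared by the probability of superiority with 2000 bootstrap resamples and, for their place, by Fisher's exact test. The 16 gene lists (495 of 496 symbols matched a gene, all but Meg3) were tested against 10000 random lists of the same size and gene lengths, a one-sided permutation test over genes, with Benjamini-Hochberg adjustment over 32 tests and a threshold of 0.05. Of the 16 lists, 7 in the cocaine and 4 in the saline list had an unadjusted p under 0.05, and 5 and 1 passed after adjustment. Some genes stand in more than 1 list, such as Crem, Creb1, Fosb, Per1 and Atf4.

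The gene lists, tests, named genes and most alternatives were fixed before the data were examined. Named genes are the 10 with peaks in both lists of highest cocaine fold, for each treatment the 10 of highest −log10 q among peaks that no peak of the other list overlaps, at genes with a peak in 1 list only, up to 4 members of each gene list by cocaine −log10 q with up to 2 found in the saline list only, and Creb1, Crem, Fos, Nr4a1, Per1, Gfap and Aqp4. Btg2, Maoa, Kdm6b, Brca1, Brd2, Gas5, Gm44805, Sphk2, Ruvbl2 and the genes first named in the closing section were chosen after their values were seen. Alternatives were stricter q and fold thresholds, other overlap rules, a 1 kb window, all annotated genes, other links of peaks to genes, other matching, minimum summit height and a cocaine list of equal length.

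The steps were tested on simulated data. All of 165 simulated heights were recovered (100%), and 200 of 200 planted shared peaks were found. Random lists of 40 genes reached p of 0.05 or less in 5.5% of cases for the cocaine list and 1% for the saline list, and lists with 12 planted genes in 100%. No gene list had more than 4 genes with a saline peak, and those not called in the cocaine list had at most 7. The power for such smaller counts was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.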

Results

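Binding of CREB, the cAMP response element binding protein, was mapped by CUT&RUN in astrocytes isolated from the brains of wildtype male C57BL/6J mice. CUT&RUN uses an antibody to bring a nuclease to a chromatin protein, and the released DNA fragments are sequenced. The mice had received saline or cocaine at 20 mg/kg by intraperitoneal injection on 7 days, and astrocytes were isolated after 24 h of withdrawal. The 16 libraries form 4 groups of 4, with a CREB and an IgG control group for each treatment. The values analysed here are 1 peak list per treatment, so no value belongs to a single library and no difference between the treatments could be tested against replicates. The IgG libraries have no values of their own in these lists and were not analysed here. Intervals on shares are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only. The reads per library are not given in the sources used here. Reads at peak summits, recovered from the deposited values, had a median of 10 (interquartile range 7 to 14) in the cocaine list and 8 (7 to 11) in the saline list.

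The first comparison asked where CREB was found in astrocytes after cocaine and after saline. The cocaine list held 2416 peaks on chromosomes 1 to 19, X and Y and the saline list 1040, a ratio of 2.32. Peaks of the cocaine list covered 851813 bp and had a median width of 287.5 bp, against 253316 bp and 150 bp in the saline list. CREB peaks of the cocaine list lay mostly at genes: 1514 summits (62.7%, 60.7 to 64.6) were within 3 kb of an end of a protein-coding gene, 7.18 times the 8.72% of randomly placed peaks. In the saline list 227 summits (21.8%, 19.4 to 24.5) lay that close, 2.60 times the 8.39% of random placement. The highest of 1000 random placements reached 10.4% for the cocaine list and 11.8% for the saline list. Random placement takes no account of open chromatin. Neither the CREB motif nor the IgG libraries were examined here, so these shares leave unchecked how specific the antibody signal was.

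Peaks of the cocaine list were also closer to the gene ends, with 39.7% of summits within 200 bp against 9.42% in the saline list. The median distance to the nearest end was 398.5 bp in the cocaine list and 24511.5 bp in the saline list. Summits inside genes but farther than 3 kb from an end made up 18.6% (17.1 to 20.2) of the cocaine list and 32.2% (29.4 to 35.1) of the saline list. Summits between genes made up 18.8% (17.2 to 20.4) and 46.0% (42.9 to 49.0). Strand was not used here, so the end nearest a summit is not called a promoter, and a promoter inside a gene counts as far from its ends.

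**Figure D1:**
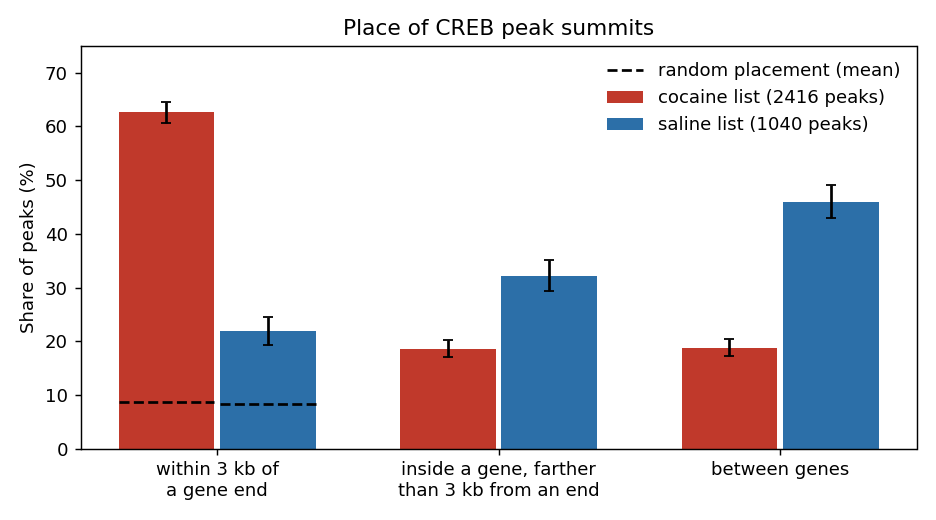
Share of CREB peak summits (%) by place in the genome for the cocaine list (red, 2416 peaks) and the saline list (blue, 1040 peaks), with exact 95% binomial intervals as error bars and dashed lines at the mean of 1000 random placements. Summits within 3 kb of a gene end make up 62.7% of the cocaine list and 21.8% of the saline list.

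The share near gene ends differed between the lists among peaks of like height as well. Among peaks with 11 to 15 reads at the summit, 416 of 580 in the cocaine list (71.7%, 67.9 to 75.4) and 42 of 144 in the saline list (29.2%, 21.9 to 37.3) lay within 3 kb of a gene end. Among the weakest peaks, with 5 to 6 reads, the shares were 47.6% and 18.5%. The peaks of 21 or more reads were near gene ends in 54.2% of 264 cases in the cocaine list and in 2.47% of 81 cases in the saline list. This class runs up to 3000 reads and leaves out peaks whose height was not recovered. It holds 56 cocaine and 51 saline peaks with a fold under 4, at places of raised background. Without them, a split chosen after the data were seen, the shares were 67.3% of 208 (60.5 to 73.6) and 3.33% of 30 (0.0844 to 17.2).

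**Figure D2:**
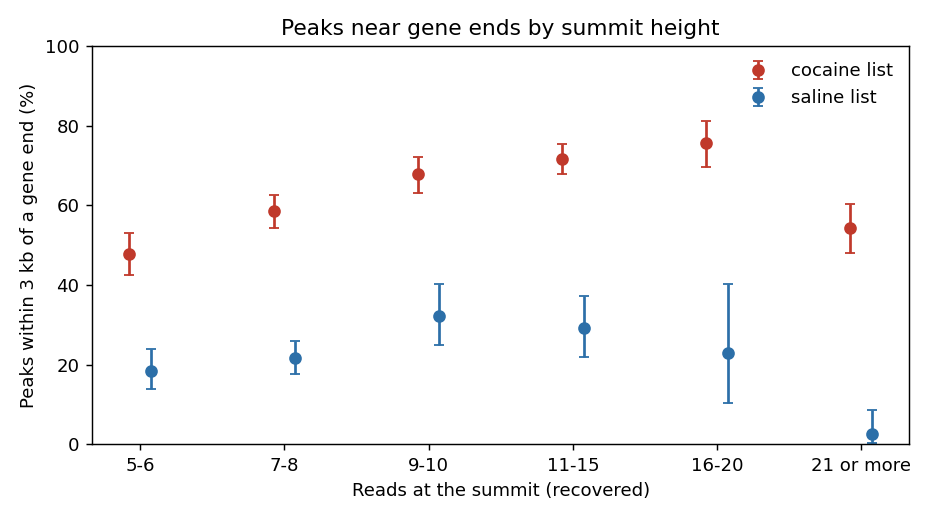
Share of peaks within 3 kb of a gene end (%, vertical axis) by recovered reads at the summit (horizontal axis) in the cocaine list (red) and the saline list (blue), with exact 95% binomial intervals. In peaks of 11 to 15 reads the share is 71.7% in the cocaine list and 29.2% in the saline list.

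The second comparison asked which CREB sites the treatments had in common. Of the saline peaks, 231 (22.2%, 19.7 to 24.9) overlapped a cocaine peak by at least 1 bp, and 232 cocaine peaks (9.60%, 8.46 to 10.8) overlapped a saline peak. No random placement came above 0.481% for the saline list or 0.207% for the cocaine list. The overlap in the saline list was concentrated at genes. Within 3 kb of a gene end 124 of 227 saline peaks (54.6%, 47.9 to 61.2) were shared, against 107 of 813 farther away (13.2%, 10.9 to 15.7; odds ratio 7.94, two-sided Fisher's exact test over peaks of this list, p = 1.42e-35). In the cocaine list the shared part was 8.19% near gene ends and 12% farther away (odds ratio 0.656, two-sided Fisher's exact test, p = 0.00268). Of the 82 cocaine peaks with a fold under 4, at places of raised background, 44 (53.7%) were shared and only 13 (15.9%) lay near gene ends. Most of the shared ones among them therefore lay farther away, and 8.05% of the remaining cocaine peaks were shared. The difference by place in the cocaine list may rest largely on the peaks with a fold under 4, and it was not tested without them. This split by place was chosen after the data were seen. Neighbouring peaks are not independent, so these p-values describe each list and not the treatments.

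Shared peaks were the higher ones in each list. Their median height in the cocaine list was 21 reads against 9 for the remaining peaks, and a shared peak was the higher of a random pair with probability 0.839 (95% bootstrap interval 0.807 to 0.867). In the saline list the medians were 10 and 7 reads and the probability 0.740 (0.704 to 0.774). Fold enrichment, which the authors' peak caller gave at each summit, separated them less, with a probability of 0.590 (0.538 to 0.640) in the cocaine list and 0.521 (0.472 to 0.567) in the saline list, an interval that includes 0.5. An overlap of at least 50% of both peaks left 10.5% of saline peaks and 4.51% of cocaine peaks shared.

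By nearest protein-coding gene, 1464 of 21887 genes (6.69%) had a cocaine peak within 3 kb of an end and 226 (1.03%) had a saline peak. Such genes are called bound here, which means only that a peak was called near an end. Both lists had a peak at 125 genes, 1339 genes had one in the cocaine list only and 101 in the saline list only. At 9 and 8 of these, every peak near an end overlapped a peak of the other list that was not given to that gene. Independent lists of these sizes would share 15.1 genes. Random draws matched on gene length shared 16.2 on average and 34 at most, and the permutation p of 1e-04 is the smallest that 10000 draws can give. The draws were not matched on CpG content, expression or open chromatin, so they compare the lists with all genes, including silent ones. The genes in both lists were 55.3% (48.6 to 61.9) of the saline genes. With the cocaine list reduced to its best 1040 peaks by q, the genes in the cocaine list only fell to 630. Genes in both lists then numbered 99, fewer than the 127 in the saline list only.

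Among the genes bound in both lists, the highest fold enrichment in the cocaine list was 37.4 at Rap2a, a small Ras-like GTPase (50 reads, chromosome 14, 120477468 to 120478436 in mm10). Its saline peak had a fold of 9.26 and 12 reads. Psmd3, a subunit of the proteasome lid, had 36.9 in the cocaine list and 6.97 in the saline list, with 69 and 12 reads. Trp53inp2, a regulator of autophagy, had 33.7 and 14.8. Both casein kinase genes of this group, Csnk1g2 and Csnk1d, had cocaine peaks with folds of 28 and 21.4 and saline peaks with 8.85 and 4.76. The autophagy receptor gene Nbr1 had 25.6 and 7.47, and an end of Brca1 lay within 3 kb of the same summit. Folds of 1700030J22Rik, Ric8b and Slc35b1 were 25.7, 24.4 and 22.0 in the cocaine list and 4.83, 6.97 and 8.88 in the saline list. Fosb, an AP-1 transcription factor gene, had a cocaine peak at its higher-coordinate end (chromosome 7, 19310025 to 19310466, fold 22.0, 29 reads) and a saline peak at the same place (19310049 to 19310310, fold 6.66, 8 reads). Fold and q depend on the background of each list, so they rank peaks within a list and were not compared between lists. These genes were picked by their cocaine fold, so higher folds there than in the saline list partly follow from the selection.

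Among peaks without a saline overlap at genes bound in the cocaine list only, the strongest by q began with H2-DMa, which encodes a chaperone of MHC class II peptide loading (chromosome 17, 34119278 to 34119910, fold 34.4, 46 reads). That summit also lies inside the gene of the bromodomain protein Brd2 (34112019 to 34122814), 3335 bp from its nearer end. Mdh2, mitochondrial malate dehydrogenase, followed with a fold of 26.4 and 35 reads 65 bp from its lower-coordinate end. Further mitochondrial protein genes of this group were Opa3 (fold 24.7) and Coa7 (fold 21.1). The group also held Inpp5a (21.6), an inositol phosphate phosphatase gene, Vapa (24.2), Larp7 (23.4), the phosphatase gene Ppm1d (22.0), the ubiquitin ligase gene Pja2 (21.3) and the topoisomerase gene Top2b (19.4). The Vapa summit lay 2718 bp from the gene's higher-coordinate end, the other summits of this group at most 273 bp from an end.

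At genes bound in the saline list only, the 10 strongest peaks without a cocaine overlap had 9 to 13 reads and were 121 to 357 bp wide. The first were at Kansl3, a subunit of a histone acetyltransferase complex (chromosome 1, 36368997 to 36369146, fold 10.4, 13 reads), and at Gcm1, a transcription factor gene (chromosome 9, 78065433 to 78065582, fold 10.4, 13 reads), and both were 150 bp wide. Zbtb37, Fancd2os and the apolipoprotein gene Apoc2 each had a fold of 8.88 and 11 reads. The Zbtb37 summit lay inside the noncoding gene Gas5. Apoc2 shares its lower-coordinate end with Gm44805, the gene to which a cocaine peak within 3 kb of that end was given, so its place in this group rests on a tie. Guk1 (fold 7.51), Duxf3 (6.96), Dock5 (7.40), Rhobtb2 (7.40) and Fam83f (7.40) completed the group. The number of genes bound in the saline list only ranged from 48 with peaks of at least 8 reads, an alternative chosen after seeing the data, to 127 with the cocaine list reduced to the length of the saline list.

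The third comparison asked which groups of genes CREB was found at, using 16 gene lists. CREB target genes stood out in both treatments. Of 40 such genes 17 had a peak near an end in the cocaine list against 2.53 expected from random genes of matched length (adjusted permutation p = 0.00107, one-sided permutation test over genes, Benjamini-Hochberg over 32 tests). In the saline list 4 of 40 had one against 0.385 expected (adjusted permutation p = 0.00320). The immediate early gene Fos had the strongest saline peak of the list (chromosome 12, 85473588 to 85473874, fold 11.1, 14 reads) and a cocaine peak over the same stretch (85473512 to 85473890, fold 19.8, 33 reads). Fosb and Btg2, an antiproliferative gene, also had peaks in both lists. Egr1 and Ier2, further immediate early genes, had cocaine peaks with a fold of 17.6 and 23 reads each and no saline peak near an end. Counts per treatment come from lists of different length, and the difference between the treatments was not tested.

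Nr4a1, an orphan nuclear receptor gene, had its saline peak 2217 bp beyond its higher-coordinate end (fold 6.66, 8 reads). Its cocaine peak lay inside the gene (chromosome 15, 101266554 to 101267073, fold 9.53, 12 reads), 8054 bp from an end, and so is not in the count of 17. Crem, which encodes a CREB relative, had 2 cocaine peaks. One lay 266 bp from its higher-coordinate end (chromosome 18, 3336807 to 3337744, fold 11.9, 18 reads) and the other inside the gene (3280798 to 3281424, fold 8.75, 13 reads). Per1, a clock gene, had 3 cocaine peaks between 69094532 and 69099159 on chromosome 11, with 25, 35 and 6 reads. Creb1 itself had a weak cocaine peak (chromosome 1, 64532733 to 64533122, fold 5.0, 7 reads). Crem, Per1 and Creb1 had no saline peak, and the astrocyte genes Gfap and Aqp4 had no peak in either list.

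**Figure D3:**
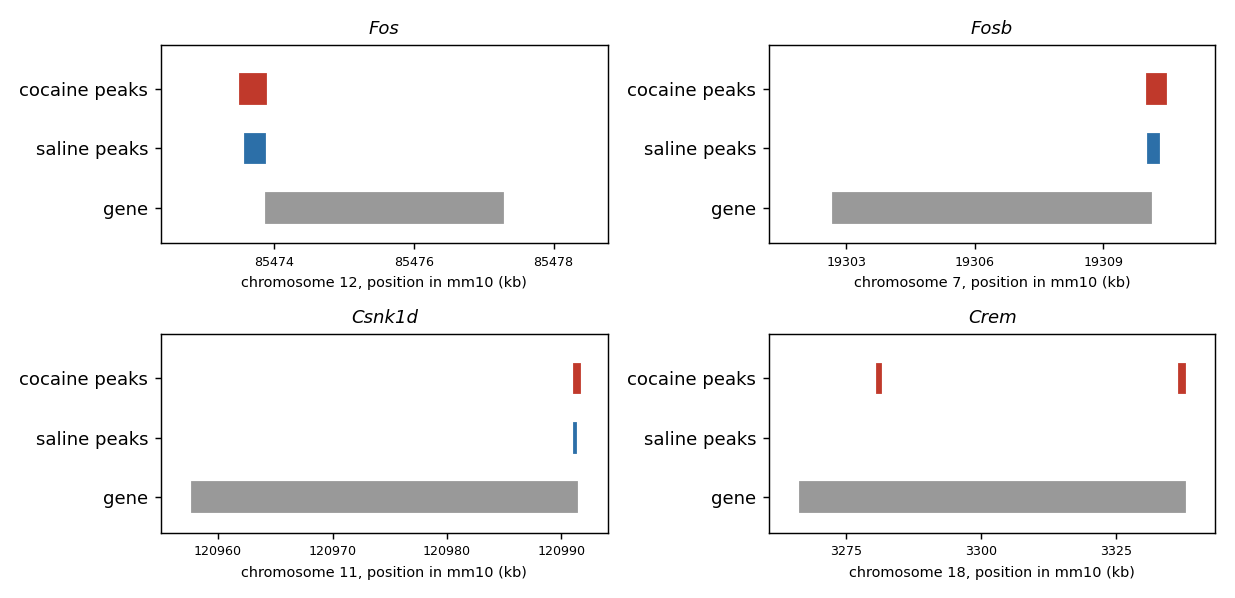
Maps of the Fos, Fosb, Csnk1d and Crem regions in mm10 (horizontal axes, position in kb), with cocaine peaks in red, saline peaks in blue and the gene in grey. Fos, Fosb and Csnk1d have overlapping peaks of both lists at one end, and Crem has 2 cocaine peaks and no saline peak.

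Genes of the cAMP and CREB pathway had a cocaine peak in 10 of 40 cases against 2.51 expected (adjusted permutation p = 0.00320), and none had a saline peak near an end. Besides Crem these included Rapgef3, a cAMP-activated exchange factor (fold 11.7, 15 reads), the transcription factor gene Atf4 (9.09, 19 reads) and the G protein gene Gnai2 (10.3, 13 reads). Genes of protein folding and stress had one in 10 of 26 cases against 1.86 expected (adjusted permutation p = 0.00107). The heat shock protein genes Hspa4 (fold 15.4) and Hspa8 (12.5) and the co-chaperone gene Dnajb9 (12.5) led this list, and again no member had a saline peak near an end. Ribosomal protein genes were bound in 9 of 40 cases in the cocaine list against 1.96 expected (adjusted permutation p = 0.00107), led by Rps9 and Rps16 (fold 11.7 each), Rpl18 (14 reads) and Rps19 (10.4). The Rpl18 summit also lies inside the neighbouring gene Sphk2. In the saline list Rps3 and Rpl13 (fold 6.66, 8 reads each) were the 2 genes of this list of 40 with a peak, against 0.289 expected (adjusted permutation p = 0.117), and neither had a cocaine peak near an end.

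Circadian clock genes had a cocaine peak in 6 of 22 cases against 1.61 expected (adjusted permutation p = 0.0171), among them Csnk1d, Per1, Nr1d2 (fold 6.37) and Cry1 (6.60). This call was lost when every gene with an end within 3 kb of a summit was counted (adjusted permutation p = 0.0709). Csnk1d and Nr1d2 also had saline peaks, against 0.254 genes expected (adjusted permutation p = 0.109). Random lists were matched on gene length and not on expression or open chromatin, so these tests compare each list with all genes, including silent ones.

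**Figure D4:**
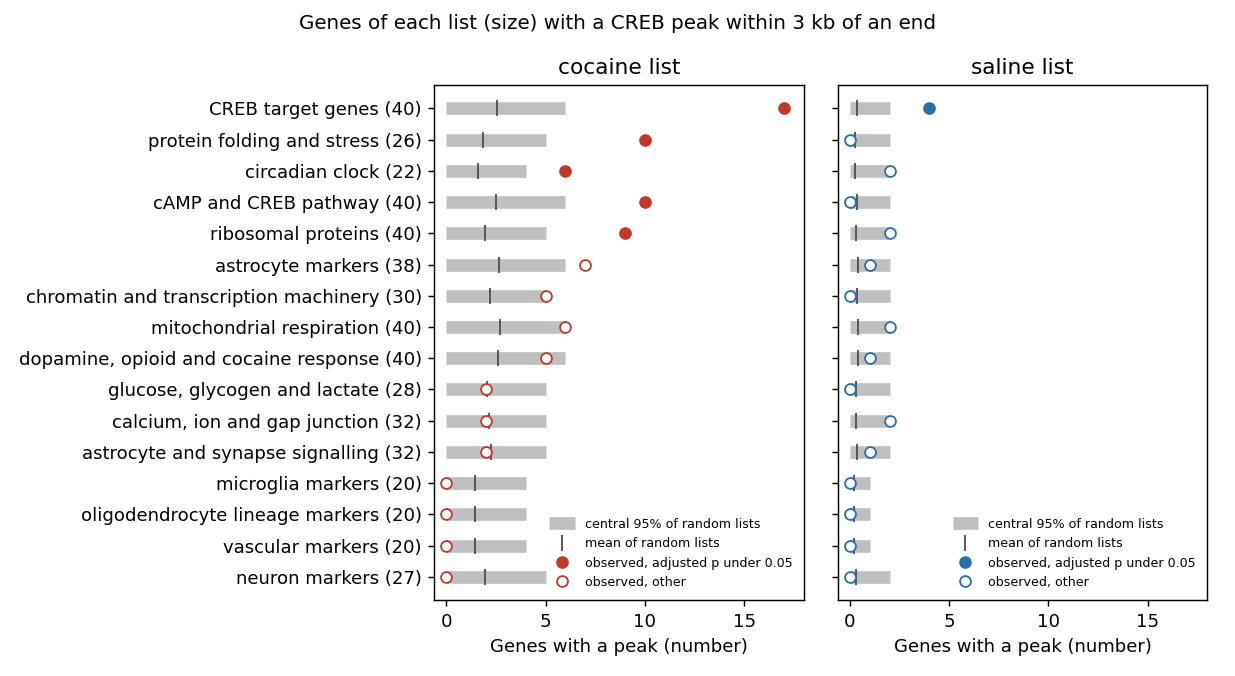
Number of genes with a CREB peak within 3 kb of an end (horizontal axis) for each of 16 gene lists (list size in brackets) in the cocaine list (left) and the saline list (right). Grey bars span the central 95% of random lists matched on gene length, ticks mark their mean, and filled points have an adjusted p under 0.05, which held for 5 lists in the cocaine list and for CREB target genes in the saline list.

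Markers of astrocytes, the cells isolated, had a cocaine peak in 7 of 38 cases against 2.64 expected and did not pass the adjusted threshold (adjusted permutation p = 0.0709). The highest folds were at Ndrg2 (9.45, 12 reads), the protease gene Htra1 (8.75, 13 reads), the apolipoprotein gene Apoe (6.22, 8 reads) and Sox9 (5.86, 7 reads). Of 5 alternatives, the astrocyte list passed in 1, when peaks anywhere in a gene or within 3 kb of it were counted (adjusted permutation p = 0.0368). In the others it did not pass, with an adjusted permutation p of up to 0.249. Htra1 was the 1 astrocyte marker with a saline peak (adjusted permutation p = 0.625), 2006 bp from its other end. No marker of neurons (27 genes), microglia (20), the oligodendrocyte lineage (20) or blood vessels (20) had a peak near an end in either list. Over these 87 markers of other cell types together, pooled after the counts were seen, random genes of matched length would give 6.21 in the cocaine list and 0.971 in the saline list.

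Other fixed lists did not pass the adjusted threshold in either list. Genes of mitochondrial respiration had a cocaine peak in 6 of 40 cases (2.70 expected, adjusted permutation p = 0.141), in order of −log10 q at Cycs, which encodes cytochrome c (fold 12.5, 19 reads), Ndufv1 (5.30), Sdhb (6.60) and Ndufa10 (6.25) first. Ndufa10 and Atp5b had saline peaks (0.428 expected, adjusted permutation p = 0.166). Genes of dopamine, opioid and cocaine response had one in 5 of 40 cases (2.62 expected, adjusted permutation p = 0.271), at Fosb, the scaffold gene Homer1 (fold 13.2, 17 reads), the histone deacetylase gene Hdac5 (5.63), the adrenergic receptor gene Adra2a (5.13) and Maoa (3.93). Fosb was the 1 member with a saline peak (adjusted permutation p = 0.625). Chromatin and transcription machinery had 5 of 30 (2.22 expected, adjusted permutation p = 0.166), at Sp1 (fold 11.8, 25 reads), Polr2a (15 reads), Ctcf (8.80), Smarca4 (7.33) and Kdm6b (6.25), and no saline peak near an end.

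In the cocaine list, lists of astrocyte output and metabolism had about as many bound genes as random lists. Of 32 genes of astrocyte and synapse signalling, Tgfb2, a growth factor gene (fold 11.7, 15 reads), and Slit1 (4.83) had a cocaine peak against 2.24 expected, and Tgfb2 also had a saline peak (adjusted permutation p = 1 and 0.625). Of 32 calcium, ion and gap junction genes, the calcium pump gene Atp2b1 (fold 20.6, 32 reads) and Orai1 (6.25) had a cocaine peak against 2.17 expected (adjusted permutation p = 1). Atp2b1 and Ryr2 had a saline peak against 0.335 expected (adjusted permutation p = 0.138). Of 28 genes of glucose, glycogen and lactate metabolism, Pdk4 (fold 7.33, 9 reads) and the glycogen synthase gene Gys1 (5.91, 12 reads) had a cocaine peak against 2.05 expected (adjusted permutation p = 1), and none had a saline peak near an end. The Gys1 summit also lies inside the neighbouring gene Ruvbl2.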

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

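All tests in this part were chosen after the results they measure were seen, except those of the pull-down efficiency and of random places. Sequences outside the comparisons differed between the lists in both directions. The mitochondrial sequence had 12 cocaine peaks and no saline peak, and an unplaced sequence assigned to chromosome 4 had 1 cocaine peak and no saline peak. Of the unplaced sequences assigned to no chromosome, one had 18 cocaine and 44 saline peaks and another 1 saline and no cocaine peak.

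The cocaine list had 2.32 times as many peaks as the saline list and a larger share near gene ends. Deeper CREB libraries after cocaine are argued against as the whole cause, since the caller's background floor per bp of the shortest peak, a stand-in for depth, was 0.807 times that of the saline list (1.04 times without dividing by width). Weak peaks at the calling threshold are argued against as the cause of the larger share, since it stayed 42.6 percentage points higher in peaks of 11 to 15 reads. A lower pull-down efficiency in the saline libraries stays open: 55.3% of saline genes also had a cocaine peak, as a thinned set of the same sites could give. A thinned set alone would not give the 809 of 1040 saline peaks that overlapped no cocaine peak. Most of these could lie at random places, as given below, so they do not decide against a lower efficiency. With 1 list per treatment a lower efficiency cannot be told apart from more CREB at genes after cocaine, which the design names and which was not tested.

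Saline peaks far from gene ends that no cocaine peak overlapped numbered 706, with a median width of 149 bp and 7 reads. Random places in the genome are argued against as the only source of the saline peaks without overlap. Of 809 such peaks, 12.7% (10.5 to 15.2) lay near gene ends against 8.32% of random placements (central 95% 6.43 to 10.3). The excess is small, so most of these peaks, the 706 far ones included, could still lie at random places. Stacks of reads about 1 fragment wide stay open for the far ones: 60.8% (57.1 to 64.4) of them were at most 150 bp wide, but at equal summit heights this share differed by −0.593 percentage points (95% bootstrap interval −11.7 to 10.1) from that of the 103 saline peaks near gene ends without overlap, an interval too wide to decide. Sites bound by CREB after saline alone stay open and were not tested.

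The strongest peaks by q were not at genes. None of the top 10 of either list lay within 3 kb of a gene end, and 6 of them in the cocaine list and 10 in the saline list had a fold under 4. Peaks with a fold under 4 had a median background 49.4 times the floor in the cocaine list (82 peaks) and 298 times in the saline list (71 peaks), but a peak at the floor with the fewest reads called already exceeds that fold, so this raised background follows from the selection and leaves its source open. Of these peaks 53.7% and 59.2% were shared. No biological explanation was tested for this pattern.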

How the results depend on the processing

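Of 71 alternative values 40 stayed within the interval or within 1.5 times the main count and 31 moved. Each is a count or share without a sign, so none could turn direction. The order of genes in both lists (125) and in the saline list only (101) turned to 99 and 127 with the cocaine list of equal length. The cocaine share near gene ends exceeded the saline share in 6 of 6 alternatives, by 2.26 to 3.46 times. Stricter thresholds moved several values. At a −log10 q of at least 3, 25.4% of saline peaks were shared and 64.7% of cocaine peaks lay near gene ends. At 5, 1485 cocaine and 447 saline peaks were left, 29.8% of saline peaks were shared, and 68.3% of cocaine and 24.6% of saline peaks lay near gene ends. An overlap of at least 50% of both peaks gave 10.5% of saline and 4.51% of cocaine peaks shared, and summits at most 200 bp apart 18.5% and 7.95%. The first of these rules is stricter by construction. With the cocaine list reduced to the best 1040 peaks, 17.1% of saline and 17.2% of cocaine peaks were shared, 630 genes were in the cocaine list only, and 70.9% of cocaine peaks lay near gene ends, a share chosen after seeing the data. A 1 kb window gave 55.6% and 16.1% near gene ends and 58 genes in the saline list only, and all annotated genes gave 69.8% and 30.9%.

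Further alternatives were chosen after seeing the data. With at least 8 reads at the summit 570 saline peaks were left, 31.4% of them shared, with 66.6% of cocaine and 24.7% of saline peaks near gene ends and 48 genes in the saline list only. Without peaks of a fold under 4, 18.5% of saline and 7.75% of cocaine peaks were shared. Near gene ends alone 54.6% and 8.19% were shared, and farther away 13.2% and 12%. The cause was not tested where the setting does not give it by construction. The number of gene lists called was 4 to 6 for the cocaine list and 1 for the saline list in 5 alternatives each, of which 3 were fixed beforehand and 2 chosen after seeing the data.

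No paired analysis was possible because each treatment has 1 list, and for the same reason no replicate was left out. Repeat exclusion, CpG matching and all motif alternatives were not run. Low summit heights limit single peaks, with 60.4% of saline and 37.8% of cocaine peaks at 8 reads or fewer, and the depth per library is not given in the sources used here.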

Other observations

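The tests of gene families here were all chosen after the peak lists were seen, over 13 families and 26 tests for each direction, with random genes matched on length. Histone genes were frequent among genes with a cocaine peak, with 12 of 83 against 3.24 expected (adjusted permutation p = 0.00260, one-sided permutation test over genes) while the saline list had 0 of 83 against 0.502 expected, too few to compare. They included H4c1 (chromosome 13, 23761156 to 23761629, fold 10.9, 23 reads), H2bc11 (fold 9.09, 19 reads) and H4c8 (fold 8.24, 27 reads). Most histone genes lie in clusters and share their peaks with neighbours, so they are not independent draws. Ubiquitin-specific protease genes had a cocaine peak in 10 of 56 cases against 3.88 expected, with Usp48 highest (fold 21.3, 33 reads). They did not pass the threshold in the adjustment made without H2-DMa (adjusted permutation p = 0.0650). In the saline list 2 of 56 had a peak against 0.590 expected (adjusted permutation p = 0.319), Usp48 among them. Genes of MHC class II and its peptide loading were first counted without H2-DMa, which the symbol pattern missed, and 3 of 9 had a cocaine peak against 0.654 expected (adjusted permutation p = 0.188). With H2-DMa, added after its peak was seen, 4 of 10 had one against 0.725 expected (adjusted permutation p = 0.0433). The added gene was known to have a peak, so this p gives no support, and passing the threshold rests on that gene. Its summit also lies inside the gene Brd2. In the adjustment with H2-DMa the ubiquitin-specific protease genes passed as well. That call also depends on the added gene and is not counted as passing here. The count includes H2-Ab1 (chromosome 17, 34262763 to 34263546, fold 19.1, 25 reads), and the 4 genes lie close together on chromosome 17, so they are not independent draws. H2-Ab1 was also the 1 gene of these 10 with a saline peak (34261616 to 34261736, fold 7.40, 9 reads), against 0.110 expected (adjusted permutation p = 0.319).

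Of the families tested, 3 had fewer genes with a cocaine peak than random genes, past the adjusted threshold. Olfactory receptor genes had 0 cocaine peaks in 1110 genes against 43.8 expected, and vomeronasal receptor genes 1 in 355 against 18.9 expected (adjusted permutation p = 0.00130 for each, one-sided for fewer). Potassium channel genes, many of them active in neurons, had 0 in 94 against 6.52 expected (adjusted permutation p = 0.00867). In the saline list none of these families passed the threshold, with 4 olfactory receptor genes against 6.69 expected, 0 vomeronasal receptor genes against 2.94 and 0 potassium channel genes against 0.998 (adjusted permutation p = 0.749, 0.271 and 1).

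A few far peaks of the cocaine list had both high fold and high q. The strongest lay on chromosome 17 from 4626167 to 4626599, 367957 bp from the nearest end of a protein-coding gene, with a fold of 37.5 and a −log10 q of 4037, and it overlapped a saline peak. Peaks on chromosome 10 (83954480 to 83954634, fold 34.8, −log10 q 1028) and chromosome 6 (125876913 to 125877236, fold 11.6, −log10 q 512) overlapped none. At like folds, peaks near genes had far lower −log10 q, with 83.3 at Rap2a (fold 37.4), 74.9 at H2-DMa (34.4) and 16.1 at Rapgef3 (11.7). Under the Poisson model a higher q at a like fold means more reads over a higher background. These far places therefore also had raised background. The start of chromosome 9, from 3000523 to 3037941, held 7 cocaine peaks, and 22 saline peaks lay there between 3000496 and 3037963. The strongest of these by q had low folds, 1.53 in the cocaine list and 3.13 in the saline list.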
